A study of Mus musculus with 63 samples.

How the data were processed

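RNA from lymph node lymphoma cells of Eµ-myc mice was hybridised to 63 Affymetrix expression arrays after labelling of 100 or 300 ng RNA, per the labels' protocols. The deposited values are log2 expression values. The submitters' processing notes name Partek 6.5 and RMA, a method that corrects background, normalizes arrays and summarises probes. The chip's scanner files were not used here, so these steps were not repeated, and RMA compresses differences of dim genes. Array medians ranged from 6.53 to 7.11, and which arrays were normalized together, with which settings, is not given in the sources used here.

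Of 35557 probe sets, 21789 had 1 gene symbol in the platform annotation, 1621 several and 12147 none listed. Of the 21789, 21698 matched a gene ID of the RefSeq table of assembly GRCm38.p6, used only for names. Probe sets with several symbols were not named. Each of 19938 genes was represented by its single-symbol probe set with the highest mean over all arrays. Of 455 list entries, 37 had no such probe set, Cdkn1a among them.

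Groups came from the treatment label. The sample mapping, the test designs, the other settings written in advance, the gene lists and the rule for named genes were fixed before the data were examined. The model was limma 3.58.1 in R 4.3.3, lmFit and eBayes with treatment and RNA input, two-sided, Benjamini-Hochberg adjusted p under 0.05. The 29 lists were tested with camera (preset correlation of 0.01), with camera at an estimated correlation and with fry. Fry's directional adjusted p was 1.34e-05 for p53 target genes, 1.31e-05 for immediate early genes and 0.0144 for G2 and mitosis genes. By camera 14 lists passed with the preset and 4 with the estimated correlation. A list score is the mean of its members after centring each gene. Scores were compared by exact permutation in each batch and, over all batches, by 100000 permutations of the group within batches. Other spread and correlation tests used 100000 permutations, or exact ones where a group held under 10 arrays. The split of arrays by Cdkn2a level was chosen after the values were seen.

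Genes named in the text are the 12 largest positive and 12 largest negative log2 fold changes among genes past the threshold with the same sign in the 100 ng arrays, and up to 4 members of each list with the smallest p. Further ones are Cdkn1a, Mdm2, Trp53, Cdkn2a, Myc, Bcl2 and Ighm, the 5 largest changes each way between RNA inputs, the 5 smallest p of the interaction and the 20 largest SDs among native lymphomas. The sex-linked genes and those of the closing tests come from their lists.

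Settings written in advance were no RNA input term, each RNA input alone, the first digit of the lymphoma number as a further term, a common median, quantile normalization, the mean of probe sets, filters on dim genes, eBayes with trend and robust, array weights, a fold change of at least 1.5 and leaving out the array titled as a repeat. The model was tested on simulated data with the arrays' design and each gene's own spread over 19938 genes. Of 100 genes changed by 0.5 (log2) it called 81, of 100 changed by 1 it called 99, and it called 4 unchanged genes. Simulated genes varied independently of each other and without a number series. The count of unchanged genes called thus does not give the rate of false calls in the real arrays. Figures were drawn with matplotlib 3.10.9.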

Results

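Eµ-myc mice carry a Myc transgene driven by the immunoglobulin heavy-chain enhancer and develop B-cell lymphomas. The 63 arrays measured gene expression in lymphoma cells from lymph nodes. Of these, 31 were labelled as taken 4 h after cyclophosphamide (CTX, a DNA-alkylating drug) and 32 were labelled native. The labels give a dose of 300 mg/kg for 29 of the treated arrays. The text of the series speaks of therapy-naive samples alone, so which arrays are treated rests on the array labels, and this doubt bears on each comparison of the groups below. Each array carried its own lymphoma number, and nothing in the labels tied an array of 1 group to an array of the other. RNA input to labelling was 100 ng for 29 CTX 4h and 15 native arrays and 300 ng for 2 CTX 4h and 17 native arrays. The labels do not settle whether native samples came from transgenic mice or from transplant recipients, so a difference of host between the groups is not excluded. No label says whether each array came from a separate mouse, so p-values measure the spread between these samples. Array medians lay between 6.53 and 7.11 on the log2 scale.

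The comparison of CTX 4h with native lymphomas asks how lymphoma samples differed shortly after the drug. Hmox1, which encodes the inducible heme oxygenase, had a log2 fold change of 1.68 ± 0.22 (SE, adjusted p = 8.87e-07). Its means were 11.25 ± 0.87 (SD, n = 31) against 9.80 ± 0.68 (SD, n = 32), and 28 of 31 treated arrays lay above the native median. The metallothionein gene Mt2 rose by 1.63 ± 0.30 (SE, adjusted p = 6.24e-04) and the monocyte chemokine gene Ccl2 by 1.33 ± 0.27 (SE, adjusted p = 0.00233). Among the genes that fell, the mitotic kinase gene Plk1 changed by -1.23 ± 0.28 (SE, adjusted p = 0.00624) and Hmmr by -1.25 ± 0.31 (SE, adjusted p = 0.0148). The histone gene H2ac4 changed by -1.37 ± 0.33 (SE, adjusted p = 0.0126) and Parpbp by -1.05 ± 0.18 (SE, adjusted p = 3.29e-04). The mitotic genes Aurka (-1.03), Tpx2 (-1.02), Kif2c (-1.01) and Prr11 (-1.03) were lower as well. So were Hyls1 (-0.99), Slc39a10 (-0.89), Uprt (-0.86) and Arhgap19 (means of 9.11 against 9.82 with RNA input not held). Adjusted p-values of these last genes ran from 1.91e-04 to 0.0374. Calls often did not hold in the 100 ng arrays alone. There Hmox1, Mt2 and Parpbp passed (adjusted p = 0.00429, 0.00511 and 0.0289), but Ccl2, Plk1, Hmmr and H2ac4 did not (0.17, 0.192, 0.254 and 0.189). The log2 fold changes of the latter genes at 100 ng were 1.02, -1.01, -1.06 and -1.23. Of the 51 genes called and named by rule, 12 kept their call there and 5 with the small nucleolar RNA score in the model.

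A batch here is the set of 300 ng arrays, or the 100 ng arrays whose lymphoma number starts with 1, 8 or 9. Small nucleolar and other small RNA genes stood among the largest increases, namely Snora20 (1.86), Snora31 (1.77), Vaultrc5 (1.76), Rnu3a (1.43), Snord15a (1.41), Snora74a (1.40) and Snora62 (1.37). Their adjusted p-values ran from 0.00832 to 0.0288. The mean of 60 such genes was higher in CTX 4h by 0.77 with RNA input in the model (permutation within RNA input, two-sided p = 8.50e-04). Within the batches starting with 1, 8 and 9 and at 300 ng it was higher by 0.15, 0.48, 0.49 and 0.75. The salivary gland genes Bpifa2 and Amy1 gave the largest fold changes. Bpifa2 rose by 2.87 ± 0.85 (SE, adjusted p = 0.0467) and Amy1 by 2.41 ± 0.71 (SE, adjusted p = 0.0466), but among the 300 ng arrays their differences were -1.63 and -0.08.

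In all, 281 genes were higher and 251 lower of 19938 tested (limma, Benjamini-Hochberg adjusted p under 0.05). Both counts depended on single arrays: without native replicate 8, the array with the lowest mean correlation to the others, they were 551 and 1034, and without CTX 4h replicate 30 they were 136 and 105. Native replicates 8 and 19 stood apart from the rest. Their Myc values were 11.39 and 10.64, against 12.36 or more in all other arrays, and their MYC target scores -1.84 and -1.86. The 100 ng arrays alone gave 30 and 20 genes, a model with the first digit of the lymphoma number 142 and 66, and one with the small nucleolar RNA score 24 and 2.

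The p53 target genes, a list of genes switched on by the DNA-damage-responsive transcription factor p53, rose together by a mean log2 change of 0.32 (camera adjusted p = 7.24e-14, or 0.00425 with an estimated correlation). With the macrophage and stromal scores in the model the mean change was 0.203, and with the small nucleolar RNA score 0.282 with 1 member called. Of its 28 measured members, 9 rose and 0 fell over all genes tested, and 14 rose when adjusted over the list alone. Sesn2, a stress-induced regulator of growth signalling, rose by 0.75 ± 0.15 (SE, adjusted p = 0.00285) and Phlda3 by 0.86 ± 0.19 (SE, adjusted p = 0.00588). The reductase gene Dcxr rose by 0.32 ± 0.07 (SE, adjusted p = 0.00372) and the DNA repair nuclease gene Ercc5 by 0.44 ± 0.09 (SE, adjusted p = 0.00414). Mdm2, the p53 antagonist, had 0.26 ± 0.10 (SE, adjusted p = 0.16). Cdkn1a and Trp53 were not analysed here. The list score was 0.13 ± 0.26 (SD, n = 31) in CTX 4h and -0.13 ± 0.13 (SD, n = 32) in native lymphomas, above the native median in 28 of 31 CTX 4h arrays. Within batches the score difference was 0.10 (exact permutation p = 0.0868, 6 against 7) for the 100 ng arrays whose lymphoma number starts with 1, 0.29 (exact permutation p = 0.0136, 9 against 3) for those starting with 8, 0.34 (exact permutation p = 0.0359, 14 against 5) for those starting with 9 and 0.73 (exact permutation p = 0.00585, 2 against 17) for the 300 ng arrays.

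Immediate early genes, the fast transcriptional response to many stimuli, rose by a mean of 0.38 (camera adjusted p = 5.02e-16, or 0.00425 with an estimated correlation). With the macrophage and stromal scores in the model the mean change was 0.261, and with the small nucleolar RNA score 0.372 with 3 members called. Of 18 members 9 passed, and 14 when adjusted over the list alone. Fos rose by 0.50 ± 0.08 (SE, adjusted p = 1.86e-04), Dusp1 by 1.10 ± 0.19 (SE, adjusted p = 3.03e-04), Jun by 0.83 ± 0.14 (SE, adjusted p = 3.20e-04) and Ier3 by 0.59 ± 0.10 (SE, adjusted p = 3.20e-04). Myc, the transgene's own gene, had -0.09 ± 0.14 (SE, adjusted p = 0.77). Within batches the score difference was 0.32 (exact permutation p = 0.0186, 6 against 7) for the 100 ng arrays whose lymphoma number starts with 1, 0.34 (exact permutation p = 0.0227, 9 against 3) for those starting with 8, 0.34 (exact permutation p = 0.0525, 14 against 5) for those starting with 9 and 0.72 (exact permutation p = 0.00585, 2 against 17) for the 300 ng arrays.

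Oxidative stress (NRF2) genes rose by a mean of 0.47 but a median of 0.14 (camera adjusted p = 8.78e-08, or 0.00425 with an estimated correlation), and 4 of 13 passed, or 5 adjusted over the list alone. These were Hmox1, Mt2, Mt1 (1.12) and Srxn1 (0.43), of which Mt1 and Mt2 are also induced by metals and glucocorticoids. With the macrophage and stromal scores in the model the mean change of the list was 0.319, and with the small nucleolar RNA score 0.446. Within batches the score difference was 0.46 (exact permutation p = 0.00816, 6 against 7) for the 100 ng arrays whose lymphoma number starts with 1, 0.50 (exact permutation p = 0.00455, 9 against 3) for those starting with 8, 0.39 (exact permutation p = 0.0757, 14 against 5) for those starting with 9 and 0.65 (exact permutation p = 0.00585, 2 against 17) for the 300 ng arrays.

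G2 and mitosis genes fell together, with a mean change of -0.65 (camera adjusted p = 1.47e-14), a call lost with the estimated correlation of 0.84 between members (adjusted p = 0.162). Of 23 members 9 passed, or 15 adjusted over the list alone. Within batches the score difference was -0.23 (exact permutation p = 0.0839, 6 against 7) for the 100 ng arrays whose lymphoma number starts with 1, -0.49 (exact permutation p = 0.132, 9 against 3) for those starting with 8, -0.06 (exact permutation p = 0.877, 14 against 5) for those starting with 9 and -1.46 (exact permutation p = 0.0175, 2 against 17) for the 300 ng arrays. With the small nucleolar RNA score in the model the mean change was -0.249 and 0 members were called by limma.

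DNA replication genes did not pass as a list (mean 0.06, camera adjusted p = 0.218), and none of its members passed, with Cdc6 at 0.30 ± 0.11 (SE, adjusted p = 0.142). DNA repair and checkpoint genes had a mean of -0.18 (camera adjusted p = 0.00368, or 0.601 with an estimated correlation). The checkpoint kinase gene Chek2 was its only member to pass, at -0.55 ± 0.12 (SE, adjusted p = 0.00639), by either adjustment. The BCL2 family and caspase list did not pass (camera adjusted p = 0.778), and its mean of -0.00649 and median of 0.016 differed in sign. Only Bcl2l11, which encodes the proapoptotic protein BIM, passed, rising by 0.64 ± 0.15 (SE, adjusted p = 0.00752). Bcl2 had -0.26 ± 0.20 (SE, adjusted p = 0.525).

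Secretory and senescence-associated genes (the secretory list below) rose by a mean of 0.44 (camera adjusted p = 6.62e-07, or 0.006 with an estimated correlation). Of its 13 members 6 passed the threshold, and 7 adjusted over the list alone. Beside Ccl2 these included Timp1 (1.02), Cxcl2 (0.91) and Cxcl1 (0.39). Macrophage markers had a mean of 0.29 (camera adjusted p = 2.55e-07, or 0.162 with an estimated correlation), stromal and endothelial markers 0.27 (3.11e-07, or 0.16) and adipocyte markers 0.81 (2.55e-07, or 0.145). Of these lists' members 2, 5 and 2 rose over all genes, and 8, 6 and 7 adjusted over the list alone. Examples are the Fc receptor gene Fcgr1 (0.51), the collagen genes Col1a1 (0.60) and Col3a1 (0.59), and Lpl (1.17). Glucocorticoid-induced genes had a mean of 0.37 (camera adjusted p = 1.85e-06, or 0.0987 with an estimated correlation). Ddit4 (0.96) and Tsc22d3 (0.53) passed, and 4 members adjusted over the list alone.

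Interferon response genes had a mean of 0.27 (camera adjusted p = 3.75e-04, or 0.528 with an estimated correlation), with 0 members past limma's threshold and 2 adjusted over the list alone. NF-kB target genes had 0.17 (0.0179, or 0.601 with an estimated correlation), with Ccl3 alone past it and 2 adjusted over the list alone. Pan-B-cell markers had -0.24 (0.00855, or 0.528 with an estimated correlation), with 0 members and 1 lower adjusted over the list alone. T-cell and NK-cell markers had -0.28 (0.0473, or 0.836 with an estimated correlation), with 0 members by either adjustment. The calls of these 4 lists were thus lost with an estimated correlation. The call of the T-cell and NK-cell list was lost on leaving out any of 29 of the 63 arrays, and that of the NF-kB list any of 4.

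Within the batches starting with 1, 8 and 9 and at 300 ng, the score differences were 0.30, 0.36, 0.29 and 1.17 for the secretory list, 0.42, 0.49, 0.19 and 0.27 for glucocorticoid-induced genes, 0.17, 0.14, 0.21 and 1.06 for macrophage and 0.11, 0.31, 0.30 and 0.66 for stromal markers. Permuting the group within batches gave adjusted p-values of 1.45e-04, 0.0154, 0.0207 and 0.0225 for them. For adipocyte markers, interferon response and NF-kB target genes the differences were -0.00101, 0.25, 0.92 and 1.51, then 0.17, 0.29, 0.27 and 0.84, then 0.04, 0.11, 0.14 and 0.70. They did not pass that permutation test (adjusted p = 0.0689, 0.163 and 0.34). Nor did DNA repair genes (-0.15, -0.14, 0.11 and -0.31), pan-B-cell markers (-0.02, -0.09, 0.21 and -0.83) and T-cell and NK-cell markers (-0.30, -0.26, -0.41 and 0.65), with adjusted p = 0.657 for each by permutation.

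The remaining lists did not pass. This changed without native replicate 8 for the MYC target, heat shock and erythroid lists, without native replicate 4 or CTX 4h replicate 25 for precursor B-cell markers, and without native replicate 10 or 15 for DNA replication genes. Their mean shifts and camera adjusted p-values were -0.10 and 0.211 for MYC target and ribosome biogenesis genes, -0.11 and 0.271 for heat shock genes, -0.03 and 0.889 for unfolded protein and integrated stress genes, -0.03 and 0.889 for circadian clock genes, -0.07 and 0.664 for glycolysis genes, -0.35 and 0.107 for precursor B-cell markers and -0.15 and 0.514 for mature B-cell markers. For the others they were -0.03 and 0.743 for plasma cell markers, -0.00147 and 0.889 for neutrophil markers, 0.07 and 0.277 for dendritic cell markers, 0.10 and 0.0939 for erythroid markers, 0.01 and 0.922 for sex-linked genes and -0.02 and 0.844 for reference genes. Members of these lists that passed when adjusted over the list alone were 2 higher erythroid genes, 2 lower heat shock genes and 1 higher circadian gene, Tef, which rose by 0.24 ± 0.06 (SE, adjusted p = 0.0246). Mean, median or test differed in sign for the unfolded protein, circadian and neutrophil lists.

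**Figure D1:**
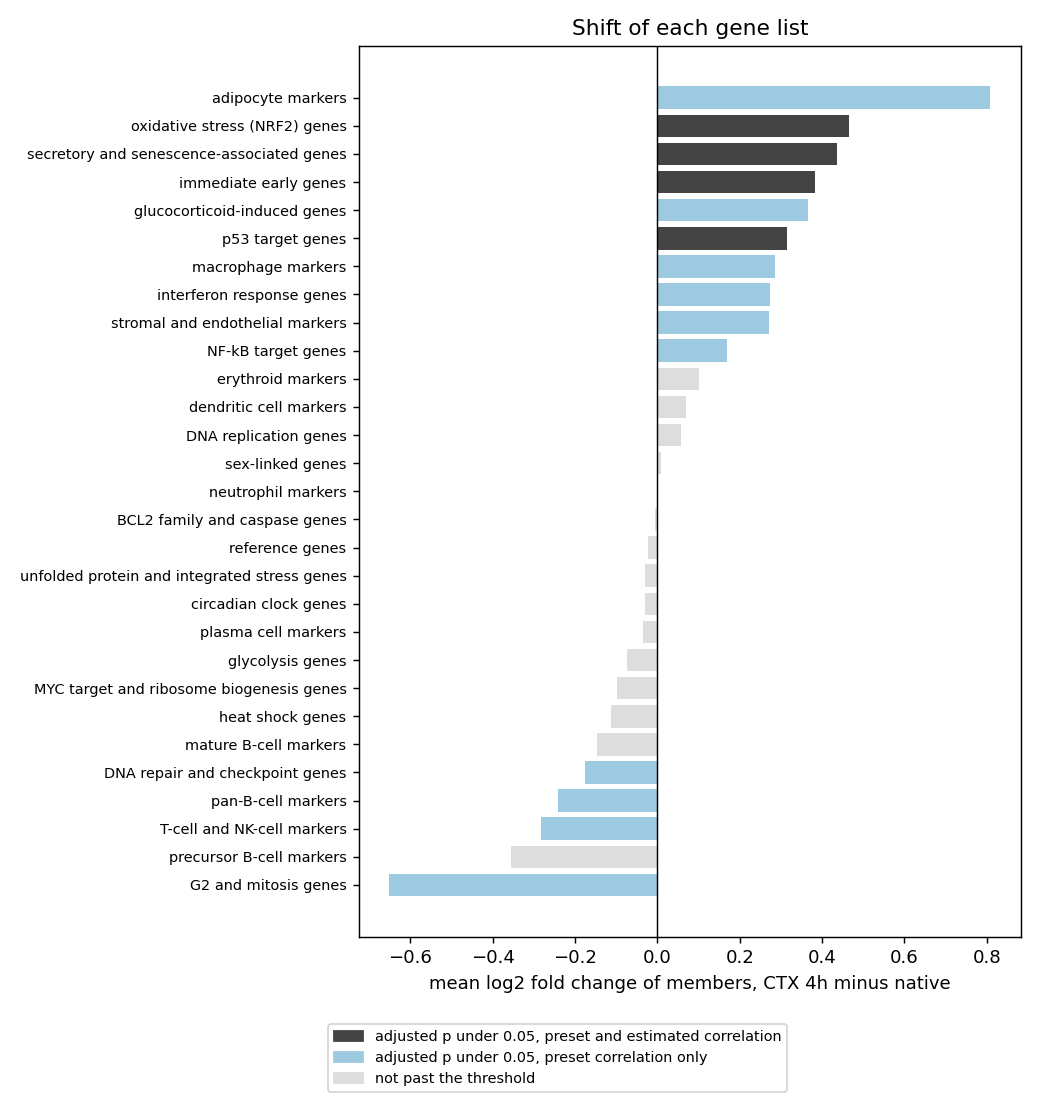
Mean log2 fold change of the members of each of 29 gene lists, CTX 4h minus native, as bars from 0. The p53, immediate early, oxidative stress and secretory lists passed with both preset and estimated correlation between genes.

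**Figure D2:**
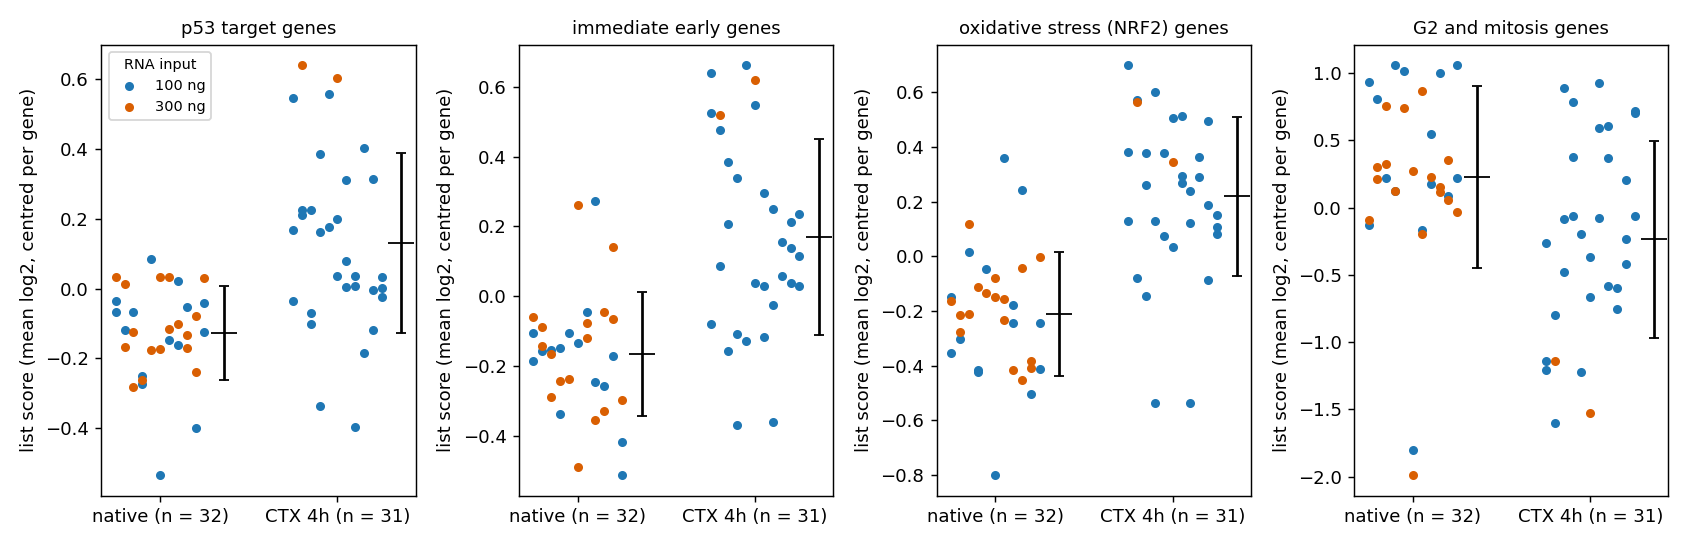
List score per array (points, mean log2 value of the members after centring each gene) for native (n = 32) and CTX 4h (n = 31) arrays, coloured by RNA input, with group mean and SD beside the points. The p53 score had a mean of 0.13 in CTX 4h and -0.13 in native arrays.

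Lymphomas differed in their p53 score, and the comparison of its spread asks whether treated lymphomas differed more. The mean absolute deviation from the median of group and RNA input was 0.167 in CTX 4h (n = 31) and 0.099 in native lymphomas (n = 32). The difference was 0.0681 (permutation test, two-sided p = 0.0328). The difference did not hold within batches. It was -0.0279, 0.0505 and 0.076 in those starting with 1, 8 and 9 (exact permutation p = 0.432, 0.423 and 0.424), and -0.0666 at 300 ng (exact permutation p = 0.193). At 300 ng CTX 4h held 2 arrays, which lie close to their own median by construction. Over the 100 ng arrays it was 0.0623 (permutation p = 0.17), and with the median of members as the score 0.0737 (permutation p = 0.0115).

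Across lymphomas, 8 relations of the p53 score were computed, 4 in each group, and whether they differ between the groups was not tested. The level of Cdkn2a, the locus that encodes the p53 activator ARF and the kinase inhibitor INK4A, fell into a lower and a higher cluster of arrays in both groups. Its relation with the p53 score is therefore given within clusters, parted at the widest gap between values of all arrays, from 9.07 to 9.45. In CTX 4h it had r = -0.39 (permutation p = 0.0958, adjusted p = 0.171) and rho = -0.24 (permutation p = 0.325, adjusted p = 0.434) in the lower cluster (n = 19). It had r = -0.18 (permutation p = 0.543, adjusted p = 0.543) and rho = -0.15 (permutation p = 0.635, adjusted p = 0.635) in the higher cluster (n = 12), so no relation was shown within either. Over all arrays the planned test passed in CTX 4h (permutation, adjusted p = 0.00184), with lower p53 score at higher Cdkn2a. Within batches it passed for numbers starting with 9 (adjusted p = 0.0022, permutation) but not for 8 or 1 (exact permutation, adjusted p = 0.943 and 0.357), and the sign was opposite for 8. The call over all arrays was lost with the macrophage score held (adjusted p = 0.0662, where its other settings over all arrays gave 0.00284 to 0.00552). It did not pass in native lymphomas (0.125). These tests span both clusters. Within a cluster the range of Cdkn2a is narrower by construction and arrays are fewer. A weaker relation there thus does not speak against the relation over all arrays. In native lymphomas it had r = -0.34 (permutation p = 0.128, adjusted p = 0.171) and rho = -0.49 (permutation p = 0.0231, adjusted p = 0.0462) in the lower cluster (n = 21), and r = -0.78 (permutation p = 0.00583, adjusted p = 0.0233) and rho = -0.79 (permutation p = 0.00578, adjusted p = 0.0231) in the higher cluster (n = 11), so that r and rho passed in the higher but only rho in the lower. Without the 2 arrays of a cluster farthest from its median p53 score, r was -0.17 (permutation p = 0.525) and -0.47 (permutation p = 0.174) in CTX 4h and -0.34 (permutation p = 0.161) and -0.52 (exact permutation p = 0.146) in native lymphomas, so the call in the native higher cluster rested on those arrays. The 3 arrays nearest the gap decide part of this. Parted at the next widest gap, from 8.48 to 8.73, r was 0.06 (adjusted p = 0.85) and -0.06 (adjusted p = 0.85) in CTX 4h and -0.57 (adjusted p = 0.0135) and -0.83 (adjusted p = 0.00324) in native lymphomas, by permutation. There the native r without the 2 farthest arrays was -0.58 and -0.69 (permutation p = 0.012 and 0.0282).

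The p53 score rose with the macrophage score in CTX 4h, with r = 0.72 (permutation p = 1e-05, adjusted p = 8e-05) and rho = 0.65 (permutation p = 1.30e-04, adjusted p = 0.00104), where 1e-05 is the smallest p the permutations can give. Without the 2 arrays farthest from the median p53 score r was 0.72. Within batches r was 0.84 (n = 14, permutation p = 2.20e-04, adjusted p = 0.0022) for numbers starting with 9, 0.61 (n = 9, exact permutation p = 0.0793, adjusted p = 0.317) for 8 and 0.12 (n = 6, exact permutation p = 0.838, adjusted p = 0.943) for 1, so it held in 1 of 3 batches. In native lymphomas (n = 32) the relation had r = 0.46 (permutation p = 0.00809, adjusted p = 0.0162) and rho = 0.32 (permutation p = 0.0784, adjusted p = 0.125). Without the 2 farthest arrays r was 0.21 (adjusted p = 0.341), so the call over all arrays rested on them. It was 0.68 among the 100 ng arrays (adjusted p = 0.013) and 0.41 after centring within batches (adjusted p = 0.0408). Within batches r was 0.24 (n = 7, exact permutation p = 0.6, adjusted p = 0.922) for numbers starting with 1 and 0.11 (n = 17, permutation p = 0.671, adjusted p = 0.943) at 300 ng, so it passed in neither alone.

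The p53 score fell with rising G2 and mitosis score in CTX 4h, with r = -0.48 (permutation p = 0.00596, adjusted p = 0.0159) and rho = -0.49 (permutation p = 0.00567, adjusted p = 0.0151). Without the 2 farthest arrays r was -0.40 (adjusted p = 0.0544, from a range of 0.0103 to 0.0544 over its alternatives), so the call rested on those arrays. Within batches r was -0.60 (n = 14, permutation p = 0.0237, adjusted p = 0.158) for numbers starting with 9, -0.18 (n = 9, exact permutation p = 0.726, adjusted p = 0.943) for 8 and 0.03 (n = 6, exact permutation p = 0.943, adjusted p = 0.943) for 1. In native lymphomas the relation did not pass over all arrays, with r = 0.23 (permutation p = 0.202, adjusted p = 0.231) and rho = 0.02 (permutation p = 0.897, adjusted p = 0.897). Among their 100 ng arrays it had r = 0.65 (permutation, adjusted p = 0.0218, from a range of 0.0218 to 0.701 over its alternatives) but rho = 0.39 (adjusted p = 0.178). That r rested on native replicate 8, without which it was 0.27 (n = 14, permutation p = 0.348). Within batches r was -0.37 (n = 7, exact permutation p = 0.397, adjusted p = 0.662) for numbers starting with 1 and -0.44 (n = 17, permutation p = 0.0603, adjusted p = 0.302) at 300 ng, of opposite sign to the r over all arrays. The T-cell and NK-cell score had r = 0.26 (permutation p = 0.155, adjusted p = 0.207) and rho = 0.29 (permutation p = 0.105, adjusted p = 0.14) in native lymphomas. In CTX 4h it had r = 0.16 (permutation p = 0.387, adjusted p = 0.387) and rho = 0.16 (permutation p = 0.389, adjusted p = 0.444). Batches of under 6 arrays of a group gave no value.

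**Figure D3:**
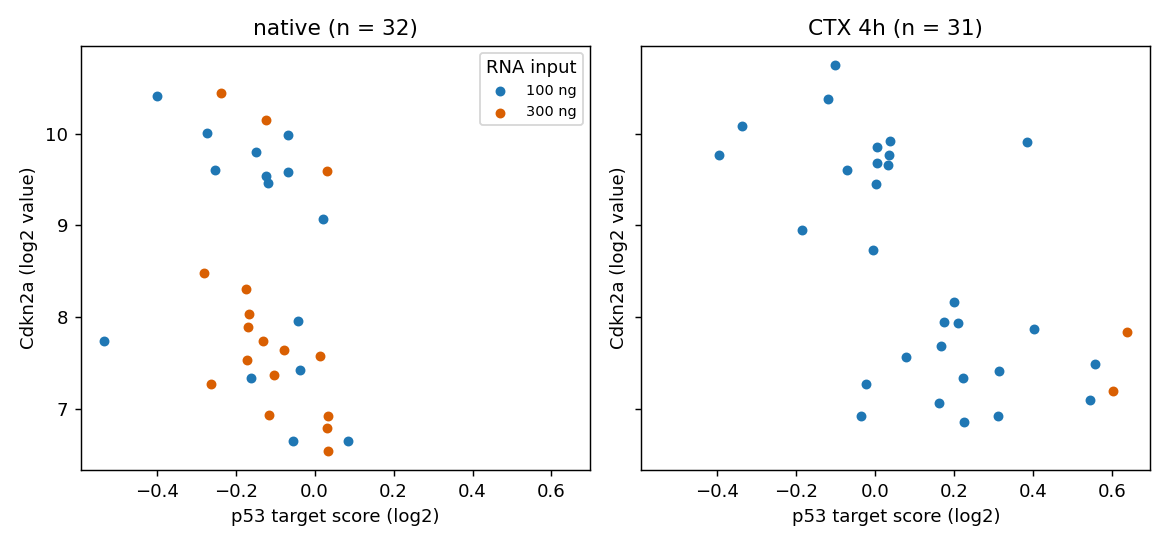
Cdkn2a value (log2) against the p53 target score (log2) per array for native (left, n = 32) and CTX 4h lymphomas (right, n = 31), coloured by RNA input. In both groups the Cdkn2a values form a lower and a higher cluster, with the widest gap over all 63 arrays from 9.07 to 9.45.

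The spread of each gene among native arrays asks where these samples differed most from each other. After centring within RNA input the SD was 2.82 for Pip, 2.66 for Car6, 2.61 for 2310057J18Rik and 2.56 for Chia1 (n = 32). It was 2.48 for Bpifa2, 2.36 for Smr3a and 2.30 for Amy1, which ranged from 4.47 to 13.97. Bpifa2 and Amy1 are salivary gland genes, and gland tissue in some samples is a possible source, given under other observations. The largest spreads thus need not be differences between lymphoma cells. The 20 most variable genes also held Igll1, part of the precursor B-cell receptor (2.05), and Ighm, the IgM heavy chain (1.65). The others of the 20 were Snord118, Cpn1, Car3, Cyp2e1, Scgb2b27, Dcpp1, Dcpp3, Cst10, Scgb1b27, 1700048O20Rik and Prol1. Cdkn2a and Ighm, named in advance, showed no difference between treatments, at -0.23 ± 0.35 (SE, adjusted p = 0.768) and -0.55 ± 0.42 (SE, adjusted p = 0.505). For Cdkn2a the group means without RNA input held were of the other sign, 8.48 against 8.33.

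Native arrays of 300 ng (n = 17) and 100 ng (n = 15) differed in 30 genes by limma, 27 higher and 3 lower at 300 ng. Bpifa2 (means of 11.18 against 6.18), Smr3a (4.13), Chia1 (3.97), Amy1 (3.92) and Cst10 (3.30) were higher at 300 ng. Prelid3a (-0.90), Ndufs5 (-0.76) and Zfand2a (-0.62) were lower. Small nucleolar RNA genes were also among the 27 higher ones, at up to 1.59, so they differed among native arrays too. With the first digit of the lymphoma number in the model limma called 0 genes, with 1831 at an unadjusted p under 0.05. All 30 genes kept their sign, with a median of 0.541 of the fold before. Bpifa2 was then at 4.01 ± 1.03, Amy1 at 3.03 ± 0.96 and Smr3a at 3.33 ± 0.99 (SE). All native arrays starting with 1 had 100 ng, while those starting with 8 or 9 had either input.

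The treatment effect differed between RNA inputs in 4 genes by limma's interaction term. It was larger at 300 ng for 1700007K13Rik (1.54, adjusted p = 0.0255), the chemokine gene Cxcl5 (1.25, 0.0397) and the myeloid receptor gene Clec12a (1.56, 0.0397). For Cep70 the 300 ng effect minus the 100 ng effect was -1.06 (adjusted p = 0.0397). Cd300a followed with 0.97 (adjusted p = 0.057) and did not pass. The CTX 4h arrays of 300 ng are also the ones whose labels give no dose, so RNA input and stated dose cannot be told apart. Only 2 CTX 4h arrays had 300 ng: without replicate 31 limma called 0 genes (569 at an unadjusted p under 0.05), and without replicate 30 it called 14.

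Xist, expressed from the inactive X chromosome of female cells, lay above a log2 value of 8 in all 63 arrays. The Y-linked gene Eif2s3y lay above 6 in 4 arrays, 2 in each group, Uty in 7 and Kdm5d in 10. The genes lay above it together in 4 arrays. The levels 6 and 8 were set after the values were seen.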

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

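The tests with the macrophage, stromal and small nucleolar RNA scores in the model, those within batches, splits included, and the interaction of lists were chosen after the result was seen. The interaction of genes and the other splits were planned.

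The effect of treatment differed between RNA inputs, by the interaction term, for 4 genes. The 300 ng effect minus the 100 ng effect was 1.54 for 1700007K13Rik, 1.56 for Clec12a, 1.25 for Cxcl5 and -1.06 for Cep70. For lists whose interaction passed with both correlation settings, the mean difference was 0.49 for p53 target genes (adjusted p = 0.00721 with an estimated correlation), 0.86 for the secretory list (9.89e-04) and 0.91 for macrophage markers (0.00831). All rest on 2 CTX 4h arrays of 300 ng, whose labels give no dose.

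In CTX 4h, p53 target and immediate early genes rose and G2 and mitosis genes fell. With macrophage and stromal scores in the model the mean shifts were 0.203, 0.261 and -0.488, with 5, 6 and 3 members called (9 each before) and adjusted p = 0.0401, 0.0401 and 0.538 at an estimated correlation, which argues against such cells as the whole cause for the first 2 lists and leaves it open for G2 and mitosis genes (0.162 without the scores). Batches of lymphoma number and RNA input are argued against for the first 2 lists. Permutation within them gave p = 1e-05 (the smallest possible) and 2e-05, with the same sign in all 4 batches. For G2 and mitosis genes it gave p = 0.0111 with the same sign, but only the 300 ng batch passed alone (exact permutation p = 0.0175, 2 against 17). With the first digit of the lymphoma number in the model their mean shift was -0.429, against -0.651 without. Batches are thus not excluded as a source of part of it. RNA quality was not measured, and stays open for all 3 lists. The small nucleolar RNA score cannot decide on it, since it also marks the number series. It lay between -1.64 and -0.948 in arrays starting with 1 and at -0.761 or more in all others. With that score in the model the shift was 0.282 for p53 target genes, though members called went from 9 to 1. It was 0.372 for immediate early genes (from 9 to 3). For G2 and mitosis genes it went from -0.651 ± 0.203 to -0.249 ± 0.195 (SE). A treatment effect on the lymphoma cells is a candidate explanation for the first 2 lists. A difference of host, of RNA quality or of other tissue in the samples stays open beside it. Adipocyte markers, with a mean shift of 0.81, were held in no model.

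Of 100 splits of the arrays within RNA input, the real one included, 1 reached the 532 calls, namely the real one, and the highest other gave 6. These splits do not hold the number series. Of 100 splits within batches, chosen after the result was seen, 3 reached it, the real one included, and the highest other gave 3382. That share does not exclude chance, since the test was chosen late and 100 splits are few. A split with several times the real count points to a structure of the samples other than treatment. The count alone is thus weak evidence of treatment. For the RNA inputs among native lymphomas 2 of 100 splits gave as many as the 30 calls. The highest other split gave 687, so arrays can part more strongly along some line other than RNA input.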

How the results depend on the processing

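Chosen after seeing the data were the settings without the 3 arrays of lowest mean correlation, without lymphomas numbered from 1, with each array left out, with small nucleolar RNA or macrophage and stromal scores, with the lymphoma digit among native arrays, with permutation or splits within batches, with correlations centred within batches, with the macrophage score held and within Cdkn2a clusters. The others were planned. The causes of the changes below were not tested, except that a fold limit reduces calls by construction. Macrophage and stromal markers give no value under their own scores.

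The p53, immediate early, oxidative stress and G2 and mitosis lists kept direction and call in all 17 settings. In 1 of these permutation within batches replaced camera, the others used camera's preset correlation, and eBayes with trend and robust does not enter camera. The G2 and mitosis call was lost with an estimated correlation (adjusted p = 0.162), and with the small nucleolar RNA score its shift was -0.249 ± 0.195 (SE). The shifts of the 4 lists ranged from 0.203 to 0.73, 0.261 to 0.72, 0.319 to 0.65 and -1.46 to -0.249.

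The 281 higher and 251 lower genes became 118 and 183 with no RNA input term, 30 and 20 at 100 ng only, 238 and 114 at 300 ng only and 142 and 66 with the first digit of the lymphoma number. They became 193 and 145 at a common median, 384 and 343 after quantile normalization, 2151 and 3677 with array weights and 108 and 46 with a fold of at least 1.5. They became 681 and 1310 without the 3 arrays of lowest correlation, 84 and 26 without lymphomas numbered from 1, 24 and 2 with the small nucleolar RNA score and 225 and 381 with the macrophage and stromal scores. The share of calls that were higher was 52.8%, against 57.1% at a common median and 52.8% after quantile normalization. All 532 called genes kept their sign at 100 ng, where 49 were called. At 300 ng 522 kept it. Leaving out each array gave 136 to 551 higher and 105 to 1034 lower genes. These arrays moved a count by over 1.5 times: 280 and 389 without native replicate 7, 551 and 1034 without native replicate 8, 202 and 146 without native replicate 9, 220 and 153 without native replicate 11, 180 and 130 without native replicate 12, 216 and 166 without native replicate 13, 186 and 143 without native replicate 14, 169 and 126 without native replicate 15, 317 and 386 without CTX 4h replicate 24, 338 and 379 without CTX 4h replicate 25, 369 and 402 without CTX 4h replicate 27, 136 and 105 without CTX 4h replicate 30, 158 and 128 without CTX 4h replicate 31.

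At 300 ng alone the counts became 55 and 0 without CTX 4h replicate 30 (458 lower at an unadjusted p under 0.05 in limma) and 60 and 12 without replicate 31, where the lone treated array is assumed to vary like the native ones. The 4 interaction genes became 2 at a common median, 14 without replicate 30 and 0 without replicate 31 (569 unadjusted in limma). The 30 genes between RNA inputs became 19 at a common median, 164 after quantile normalization and 0 with the lymphoma digit (1831 unadjusted in limma).

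The spread difference of the p53 score was 0.0623 (permutation p = 0.17) at 100 ng. Without the 2 farthest arrays r was 0.213 for the macrophage score in native and -0.402 for the G2 and mitosis score in CTX 4h lymphomas. At 100 ng the latter relation in native lymphomas had r = 0.653 (adjusted p = 0.0218, against 0.0218 to 0.701 over its alternatives), while rho did not pass and r was 0.273 without native replicate 8, a setting chosen after seeing the data. For Cdkn2a in CTX 4h, r was -0.393 and -0.184 within the lower and higher cluster, or 0.0573 and -0.0557 at the next widest gap, and the partial r over both with the macrophage score held was -0.384 (adjusted p = 0.0662), so the call was lost in each. In native lymphomas it was -0.775 in the higher cluster, or -0.575 and -0.829 in the lower and higher at the next widest gap.

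Reversed at 300 ng were Bpifa2 (-1.63), Amy1 (-0.0819), neutrophil markers (0.558) and T-cell and NK-cell markers (0.651), and neutrophil markers with no RNA input term (0.193). Reversed with the small nucleolar RNA score were BCL2 family (0.0749), unfolded protein (0.0712), circadian (0.0844), glycolysis (0.109), pan-B-cell (0.0409), neutrophil (0.255) and reference genes (0.0600). With the macrophage and stromal scores NF-kB targets were reversed (-0.0614). No paired analysis was possible because the labels give each array its own lymphoma number. Signal over background was not measured here.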

Other observations

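The comparison of Amy1 and Bpifa2 with further markers was written before the result was seen. The neighbour tests were chosen after the neighbours had been examined, and the one for RNA input replaced a test on values from which RNA input had been removed, which could not answer the question.

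Salivary transcripts were high in some arrays of both groups. The mean of 12 further salivary and epithelial markers, a list fixed before the test, correlated with the mean of Amy1 and Bpifa2 over 63 arrays at r = 0.638 (permutation p = 1e-05, the smallest possible) and rho = 0.73 (permutation p = 1e-05), and at r = 0.61 without the 2 farthest arrays. At 300 ng r was 0.61 (permutation p = 0.00115). In the 100 ng batches r was 0.40 (permutation p = 0.0907), 0.01 (permutation p = 0.984) and -0.06 (permutation p = 0.866) for numbers starting with 9, 8 and 1. It passed in none of these, and for 9 rho was 0.48 (permutation p = 0.0383, adjusted p = 0.051). For 1 the value cannot decide, since Amy1 lay only between 4.47 and 5.22 there. Lpo reached 11.44 and Krt18 10.81, whereas Smgc had r = -0.16 with Amy1 and Bpifa2. Salivary gland tissue taken along with cervical nodes may account for these transcripts at 300 ng, and no biological alternative was tested. Bpifa2 also reached 14.95 at 100 ng (CTX 4h replicate 17), where the markers do not settle the source.

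Mutual nearest neighbours among the arrays were taken over the 1000 most variable genes after removing RNA input and number series. They formed 20 pairs, of which 16 joined a CTX 4h and a native array. The CTX 4h array had the lower G2 and mitosis score in 16 and the higher p53 score in 11 of these. In 6 of the 16 pairs both arrays belonged to the same batch. Permuting groups within batches gave 12.3 cross-group pairs on average (one-sided p = 0.0588), so an excess of such pairs was not shown. The batches hold the groups unequally, which leaves this test little room to show 1. Over all genes as deposited, CTX 4h replicates 24 to 29 each had their highest correlation (0.990 to 0.995) with a native array starting with 1. Elsewhere such matches also joined arrays of 1 group, as for CTX 4h replicates 9 and 11 (0.989). In the values as deposited 47.4% of 19 pairs shared RNA input, against 57.2% by permutation (one-sided p = 0.888), which argues against RNA input as the source of the pairs. With X- and Y-linked marker genes left out of the search, the cross-group pairs differed in Eif2s3y and Uty by 0.395 of the difference of all cross-group arrays (permutation p = 6.20e-04, one-sided, batches not held). The same lymphoma sampled under different numbers in both groups may be a source of this, as may different lymphomas of mice of the same sex, and no array was paired by it.

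Among the 13768 probe sets without a single gene symbol, 225 were higher and 130 lower in CTX 4h by the same limma model.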
